A study of Homo sapiens with 8 samples.

How the data were processed

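RNA was measured in 4 HEK293 cell lines, each on 1 array without and 1 array with doxycycline, giving 8 arrays. HEK293 is an established human embryonic kidney line. Per the labels, the lines carried a doxycycline-inducible copy of HNF4α2, an isoform of a nuclear receptor transcription factor of liver and kidney, put into 1 genomic site by recombination. Cell lines 1 and 4 carried the wild type, another line 1 carried the mutant C106R, and line 6 carried the mutant R154X. The doxycycline dose was 1 µg/ml for 24 h, and noninduced cells received the solvent, per the labels' protocols. Biotin-labelled RNA was hybridised to Affymetrix arrays of 54675 probe sets.

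The deposited intensity of each probe set was a linear signal made with MAS5, per the submitters' processing notes. The MAS5 version and the background settings are not given in the sources used here. On each of the 8 arrays the mean signal, after trimming 2% from each end, was 1000, so the arrays had been scaled to a common target before deposit. This scaling removes a change in total RNA per cell from the values. Array medians ran from 149.6 to 169.4, and the correlation of log2 signals between any 2 arrays ran from 0.945 to 0.974. No 2 arrays held identical values. Precision is limited by the number of arrays. Detection calls were not used here, so folds from a low baseline rest on signals that may lie near background.

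Probe sets were named from the platform annotation given with the data, with symbols updated through Entrez identifiers in the RefSeq gene table. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. Of the first kind, 41043 had an identifier in the RefSeq table. No gene was named from a probe set with several symbols. The induced gene itself had 0 named probe sets and is not reported here, so expression of the transgene was not checked.

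The signals were analysed as log2(signal + 14.0), where 14.0 is the 10th percentile of all signals, and log2 changes are on this scale, which understates the change of low genes. Probe sets at or above the array's own median on at least 2 of the 8 arrays were kept, and the 62 control probe sets were left out. This left 30511 probe sets and 13441 named genes. A gene that is low elsewhere could pass the filter through its rise on the 2 induced wild-type arrays alone. Low genes that did not rise were left out, so the shares of rises and the medians of the gene lists below may be tilted upward. A linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, and an adjusted p below 0.05 counted as a call. All adjusted p-values come from limma, apart from those of the Fisher's exact tests of solute carriers, which were adjusted by the same method. The 2 residual degrees of freedom came from the 2 wild-type lines, which are separate cell lines (n = 2). Each mutant group held 1 array, which was assumed to vary like the wild-type arrays.

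The labels tie each induced array to the noninduced array of its own line, so the arrays are paired by cell line. Deviations of the 2 wild-type lines from their group means correlated at 0.278 between noninduced and induced arrays, across probe sets. The fit chosen before the data were examined had no block. The paired fit held cell line as a block over all 4 lines, with 1 induction effect for the wild type and 1 for both mutants, and also left 2 residual degrees of freedom. Of these degrees of freedom, 1 came from the 2 wild-type lines and 1 from the difference between C106R and R154X, so the 2 mutants were treated as replicates. The median residual SD of the paired fit was 0.154, against 0.227 without the block, where it came from the wild-type lines alone. The 2 SDs thus rest on different arrays and do not measure the gain from pairing alone. Blocked values are printed where they changed a call or moved a count by over 1.5 times.

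Per the file headers, all arrays came from 1 chip lot and were hybridised on 1 day and scanned on 1 day. The hybridisation times fell into 2 runs, 1 for the wild-type arrays and 1 for the mutant arrays. Each induction contrast lay within a run. Run and construct cannot be told apart in the difference between wild-type and mutant lines.

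The 20 gene lists were fixed before the data were examined, with 1 probe set per gene, the one with the highest mean log2 signal. Each list was described by its calls over all probe sets, its calls adjusted over the list alone, its median, and limma's camera test with a preset correlation of 0.01 between genes and with an estimated correlation, adjusted over the 20 lists. With an estimated correlation the test rests on the 2 residual degrees of freedom and has little power. No list passed it for the wild-type induction, where the lowest adjusted p was 0.294. A failure to pass it therefore decides nothing about a list. The rule for named genes was also fixed before the data were examined. It took the 15 largest rises and up to 10 falls among calls that had the same direction in both wild-type lines, 1 probe set per gene. It took the 5 largest rises and the 5 largest falls of each mutant, and the 5 smallest p-values in each direction for the difference where 0 passed. It took up to 4 members of each list by size of the wild-type change. Genes named outside this rule are said to be so.

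The fits were tested on simulated arrays of 30511 probe sets, with 200 changed in the wild-type induction and 10 draws. Without the block, 24.5% of the 2-fold and 74% of the 4-fold changes were called, with 0.3 false calls per draw. With the block, 64.4% and 88.3% were called, with 8.8 false calls among 161.5 per draw. With no change simulated, the mean number of calls was 0 without the block and 0.6 with it. The simulated noise was normal, with an SD set by signal level alone and the same in wild-type and mutant lines. Real probe sets of like signal may differ in SD, and more than 200 were called with the block in the real data. These rates may therefore not hold for the real calls. Alternatives were no offset or the 25th percentile as offset, no filter or a filter at the 75th percentile, quantile normalization, equal array medians, the block, no intensity trend, 1 probe set per gene, and leaving out each wild-type array. The blocked fits without either mutant line were added after seeing the data.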

Results

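Gene expression was measured on 8 arrays, an induced and a noninduced array from each of 4 HEK293 lines. The wild-type form of HNF4α2 was represented by 2 lines and each of the mutants C106R and R154X by 1 line. The series set out to find genes regulated by HNF4α2 by comparing induced with noninduced cells. The noninduced arrays gave the background for every change below. Wild-type values are means over 2 cell lines (n = 2), and the mutant arrays had no replicates.

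Induction of wild-type HNF4α2 was followed by rises of 27 named genes and falls of 2. CIDEB, a lipid droplet protein of hepatocytes, rose by 4.85 ± 0.44 on the log2 scale (SE, n = 2), from a signal of 195 ± 123 to 5470 ± 173 (SD). PPP1R1A, an inhibitor of protein phosphatase 1, rose by 3.13 ± 0.21, and DDAH2, of the dimethylarginine dimethylaminohydrolase family, by 2.90 ± 0.24. The organic anion transporter SLCO4C1 rose by 2.78 ± 0.23, the drug efflux pump ABCB1 by 1.79 ± 0.18 and the aquaporin AQP11 by 2.48 ± 0.27. The receptor ERBB3 rose by 2.63 ± 0.21, the intermediate filament gene PRPH by 2.65 ± 0.23 and the actin nucleator COBL by 1.78 ± 0.20.

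The other named rises were RBKS, which encodes ribokinase, at 2.55 ± 0.27, and GCHFR, a regulator of tetrahydrobiopterin synthesis, at 1.78 ± 0.17. TRIM10 rose by 2.53 ± 0.27, C1orf115 by 2.32 ± 0.23, GRTP1 by 2.28 ± 0.19 and TMT1B by 2.11 ± 0.20. The transcription factor gene EBF2 fell by 2.12 on the log2 scale (SE 0.22), from a signal of 567 to 120, and LGR5, a receptor of the Wnt pathway, fell by 2.05 (SE 0.20), from 3077 to 742. Each of these 17 genes changed in the same direction in both wild-type lines, with limma adjusted p-values between 0.0249 and 0.0399. The second probe sets of PPP1R1A, RBKS, SLCO4C1, ABCB1, COBL and GRTP1 had log2 changes of 3.53, 3.32, 2.08, 1.91, 1.85 and 1.05, and those of EBF2 and LGR5 had -2.34 and -1.52. The further probe sets of DDAH2 lay at 2.66 and 3.33, those of TRIM10 at 1.61 and 2.15, and those of ERBB3 at 0.07 and 1.84.

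**Figure D1:**
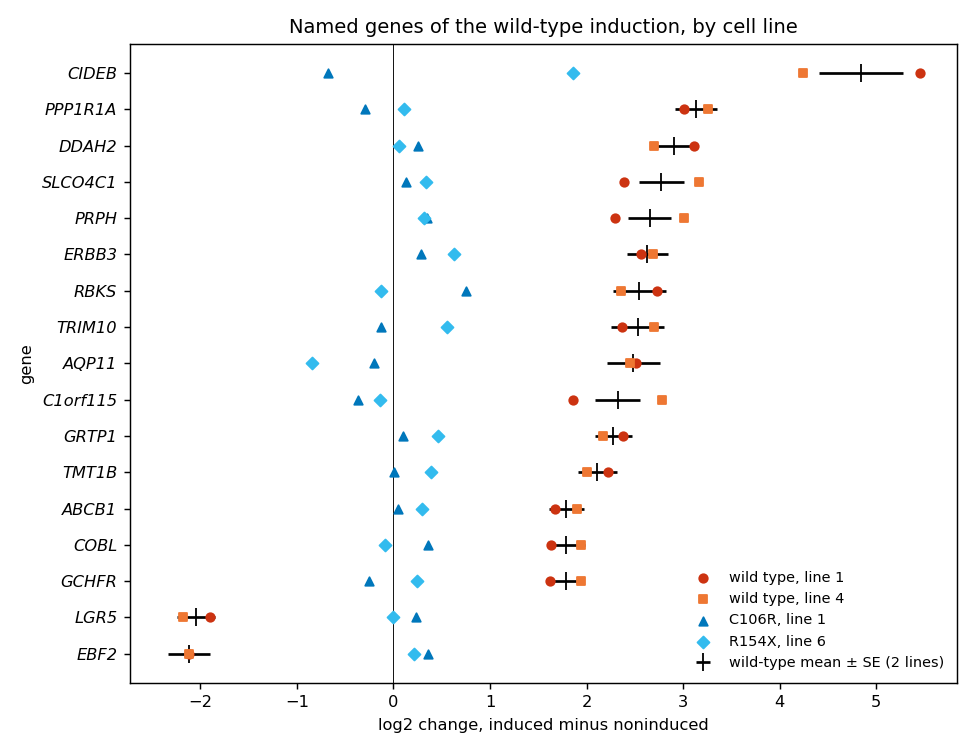
Log2 change on induction (x axis, induced minus noninduced) for the 17 named genes (y axis) in each of the 4 lines, with the wild-type mean ± SE as a bar. The wild-type points of CIDEB lie at 5.45 and 4.24 and its mutant points at -0.68 and 1.86, and both wild-type points of EBF2 lie at -2.12.

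In all, 35 probe sets passed the threshold, 33 higher and 2 lower after induction, and they named 27 genes that rose and 2 that fell. With cell line as a block in the paired fit, 2574 probe sets passed, 1323 higher and 1251 lower, among them all 35. SEs below are from the fit without the block unless given as block SE. Of the 2574, 547 changed at least 2-fold. The count without the block was 0 when either induced wild-type array was left out, and it was 71 without the noninduced array of line 1 and 41 without that of line 4. It was also 0 without the filter on dim probe sets and 0 without the intensity trend.

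Genes of fatty acid oxidation were higher after wild-type induction. The list's adjusted p was 8.0e-09 with camera's preset correlation and adjusted p = 0.294 with an estimated correlation. Of 27 measured genes, 0 passed over all probe sets, with 11 at an unadjusted limma p under 0.05. When adjusted over the list alone, 10 rose and 0 fell. With cell line as a block, 12 rose over all probe sets and 0 fell. These 12 included the mitochondrial carnitine carrier SLC25A20 at 1.24 ± 0.12 (block SE, as for the next 3), the peroxisomal enzyme EHHADH at 1.03 ± 0.16, the acyl-CoA dehydrogenase ACADVL at 0.97 ± 0.10 and the electron transfer enzyme ETFDH at 0.91 ± 0.17.

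The epithelial list was also higher (adjusted p = 1.06e-04, and adjusted p = 0.300 with an estimated correlation). Of 26 measured epithelial genes, 6 rose adjusted over the list alone and 9 with the block. These included ESPN at 3.37 ± 0.77 and MYO1A at 2.45 ± 0.46, both of the microvillus, and the transcription factor gene OVOL2 at 1.19 ± 0.25. The noninduced wild-type signal of ESPN was 21.7, below the array medians, and ESPN also changed by 1.88 with C106R and 0.98 with R154X. The chosen probe set of VIL1, at 1.85 ± 0.77, did not pass. The other 3 probe sets of VIL1 past the filter all rose in the wild-type mean, by between 1.16 and 5.22. The proximal tubule list was higher (adjusted p = 6.81e-04, adjusted p = 0.294 with an estimated correlation, and adjusted p = 0.0648 without the filter on dim probe sets, over 37 genes). Of its 15 genes that passed the filter, 5 rose adjusted over the list alone and 4 with the block. Their median change was 0.329, against 0.122 over the 37 genes without the filter. Genes that passed the filter only because they rose may account for part of this. The membrane peptidase MME changed by 1.68 ± 0.32 and passed both ways, the amino acid transporter gene SLC7A7 changed by 1.83 ± 0.52 and passed over the list alone, and GGT1 at 1.74 ± 0.71 and SLC5A2 at 1.21 ± 0.82 passed neither. The amino acid and urea metabolism list was higher, with the same adjusted p-values of 6.81e-04 and 0.294. Of its 25 genes, 4 rose adjusted over the list alone. With the block, 5 rose and CBS, named after its value was seen, fell by 0.48. ALDH5A1, of GABA breakdown, rose by 1.28 ± 0.15 and the urea cycle enzyme ASS1 by 1.12 ± 0.17 in both counts, while OTC at 3.17 ± 1.04 and DDC at 1.39 ± 0.49 did not pass.

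The drug and bile acid metabolism list was higher (adjusted p = 0.0165, and adjusted p = 0.316 with an estimated correlation). Of its 16 genes, 2 rose adjusted over the list alone and 3 with the block. The drug-metabolising enzymes NAT2, at 3.25 ± 0.80, and SULT2A1, at 2.87 ± 0.40, were in both counts, and CYP3A4 at 1.56 ± 0.51 and ADH4 at 1.40 ± 0.69 were in neither. The baseline signals of NAT2 and SULT2A1 were 70.0 and 131, below the array medians. SULT2A1 also changed by 2.14 with R154X and 0.50 with C106R, and NAT2 by -0.28 and -2.09. None of the epithelial, proximal tubule, amino acid and drug metabolism lists had a member past the threshold over all probe sets without the block, with 8, 6, 6 and 4 members at an unadjusted limma p under 0.05. The drug metabolism list's adjusted p was 0.0748 without the induced array of line 4.

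Neuronal genes that HEK293 cells express were lower after wild-type induction. The list's adjusted p was 0.00101 with the preset correlation and adjusted p = 0.294 with an estimated correlation. Of 17 measured, 6 fell adjusted over the list alone, and with the block 6 fell and TUBB3, named after its value was seen, rose by 0.39. Over all probe sets without the block 0 passed, with 7 at an unadjusted limma p under 0.05. The cytoskeletal gene MAP2 fell by 1.86 (SE 0.42), the synaptic genes NRXN3 and SNAP25 fell by 1.16 (SE 0.18) and 1.05 (SE 0.29), and RBFOX1 at -1.24 ± 0.78 did not pass. Other probe sets changed by -0.94 for MAP2, -0.14 for SNAP25, and -2.07 and 0.34 for NRXN3.

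The tests of 3 further lists passed with the preset correlation. The list of cell cycle inhibitors and p53 targets was higher (adjusted p = 0.0293, and adjusted p = 0.341 with an estimated correlation), with 5 of 29 genes risen with the block, including the oxidoreductase TP53I3 at 1.49 ± 0.17 (block SE, as for the next 2), the repair gene XPC at 0.60 ± 0.12 and the death receptor FAS at 0.56 ± 0.13, while TP53INP1 at 0.70 ± 0.27 did not pass. The list's median change was 0.095 in the wild-type and 0.094 in the mutant lines (adjusted p of the difference 0.251 with the block). Of the 4 other probe sets of FAS 3 also rose in the wild-type lines, and the 4 changes ran from -0.34 to 0.73. The respiratory chain list was higher (adjusted p = 0.0293, and adjusted p = 0.580 with an estimated correlation), with 2 of 30 genes risen with the block, the ATP synthase genes ATP5MC1 at 0.50 and ATP5MC3 at 0.31 (block SE 0.076 for both). NDUFA2 at 0.25 ± 0.12 and NDUFB3 at 0.24 ± 0.12 did not pass. The integrated stress response list was lower (adjusted p = 0.0293, and adjusted p = 0.359 with an estimated correlation), with 2 of 29 genes fallen with the block, STC2 by 0.83 and the amino acid transporter gene SLC7A5 by 0.65. CHAC1 at -0.91 ± 0.34 and VLDLR at -0.79 ± 0.31 did not pass. The list's median change was -0.084 in the wild-type and -0.073 in the mutant lines (adjusted p of the difference 0.259 with the block).

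In these 3 lists 0 genes passed without the block, over all probe sets or over the list alone, with 7, 2 and 5 at an unadjusted limma p under 0.05. The adjusted p of the inhibitor list was 0.172 without the induced array of line 1 and 0.139 without the noninduced array of line 4. That of the respiratory chain list was 0.614 without the noninduced and 0.317 without the induced array of line 1. That of the stress response list was 0.0684 and 0.0638 without the noninduced arrays of lines 1 and 4 and 0.160 without the induced array of line 4.

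The other 11 lists did not pass, with adjusted camera p-values from 0.0529 to 0.940. Cholesterol synthesis genes went both ways. EBP, a sterol isomerase, rose by 1.35 ± 0.12 over all probe sets (adjusted p = 0.0254). Of its 3 other probe sets 2 also rose, and the 3 changes ran from -0.18 to 1.23. Over the list alone DHCR7, at 0.64 ± 0.16, also rose and SQLE, an epoxidase of the same pathway named after its value was seen, fell by 0.55 (SE 0.12). With the block, 3 of 19 rose and 4 fell, INSIG1 among them by 0.74, and SREBF1 at -0.89 ± 0.33 did not pass. Of 28 liver and kidney transcription factors, 5 rose and 1 fell adjusted over the list alone, and 5 rose and 3 fell with the block. Risen in both counts were MLXIPL at 2.37 ± 0.60, a regulator of glucose-responsive genes, the oxysterol receptor gene NR1H3 at 1.15 ± 0.29 and WT1 at 1.05 ± 0.24, while FOXA2 fell by 1.91 (block SE 0.46) with the block. This list's median was -0.03 and its mean 0.03. Of 31 hypoxia and glycolysis genes, 6 rose and 4 fell with the block. ENO2, a neuronal enolase, fell by 1.00 (SE 0.18) and NDRG1 rose by 0.91 ± 0.21, and both passed over the list alone. SLC2A3, a glucose transporter gene, at 0.96 (block SE 0.23) rose with the block, and ANKRD37 at 0.62 ± 0.27 did not pass.

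Of 26 TGF-β and Wnt targets, LGR5 fell over all probe sets, and 3 rose and 6 fell with the block. The growth factor gene TGFA rose by 1.51 (block SE 0.19) with the block, while its other probe set changed by 0.02. TGFBI at 2.26 ± 0.94 and NKD1 at 1.22 ± 0.67 did not pass. Of 40 proliferation genes, 2 rose and 4 fell with the block. The phosphatase gene CDC25C rose by 0.69, the kinesin gene KIF11 fell by 0.39 and the cyclin gene CCNE1 by 0.34, and CENPF at -0.37 ± 0.37 did not pass. Of 20 mesenchymal genes, 1 rose and 2 fell with the block, and COL1A2 at -1.69 ± 0.76, S100A4 at -1.39 ± 0.86 and TAGLN at 1.10 ± 0.80 did not pass, while ZEB2 fell by 0.90 (block SE 0.20). Of 25 chaperones and genes of the unfolded protein response, 1 rose and 3 fell with the block, CRELD2 by 0.57 and HERPUD1 by 0.45, and SDF2L1 at -0.41 ± 0.21 and HYOU1 at -0.38 ± 0.19 did not pass. In these last 3 lists 0 genes passed without the block, with 4, 4 and 2 at an unadjusted limma p under 0.05.

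No hepatic secreted protein gene passed in either fit. Of 35 listed, 14 were measured, with 1 at an unadjusted limma p under 0.05. The coagulation factor gene F10 changed by 2.42 ± 0.72 (adjusted p = 0.320, and 0.0538 with the block), F7 by 0.89 ± 0.39, AMBP by -0.98 ± 0.66 and TTR by -0.66 ± 1.17. Of 15 interferon genes, IFIT5 fell by 0.43 with the block, while IFIT1 at -0.86 ± 0.38, IFI35 at 0.69 ± 0.37 and RIGI at 0.42 ± 0.30 did not pass. Of 17 housekeeping genes, B2M rose by 0.40 (block SE 0.074) with the block, and POLR2A at 0.33 ± 0.18, TBP at 0.27 ± 0.17 and YWHAZ at -0.22 ± 0.15 did not pass. The housekeeping list's median was -0.0048 and its mean 0.040. Of 21 immune, blood and endothelial markers, 3 were measured and 0 passed, CSF1R at 0.71 ± 0.74, PECAM1 at 0.61 ± 0.35 and HBB at 0.32 ± 0.18, with 0 at an unadjusted limma p under 0.05.

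**Figure D2:**
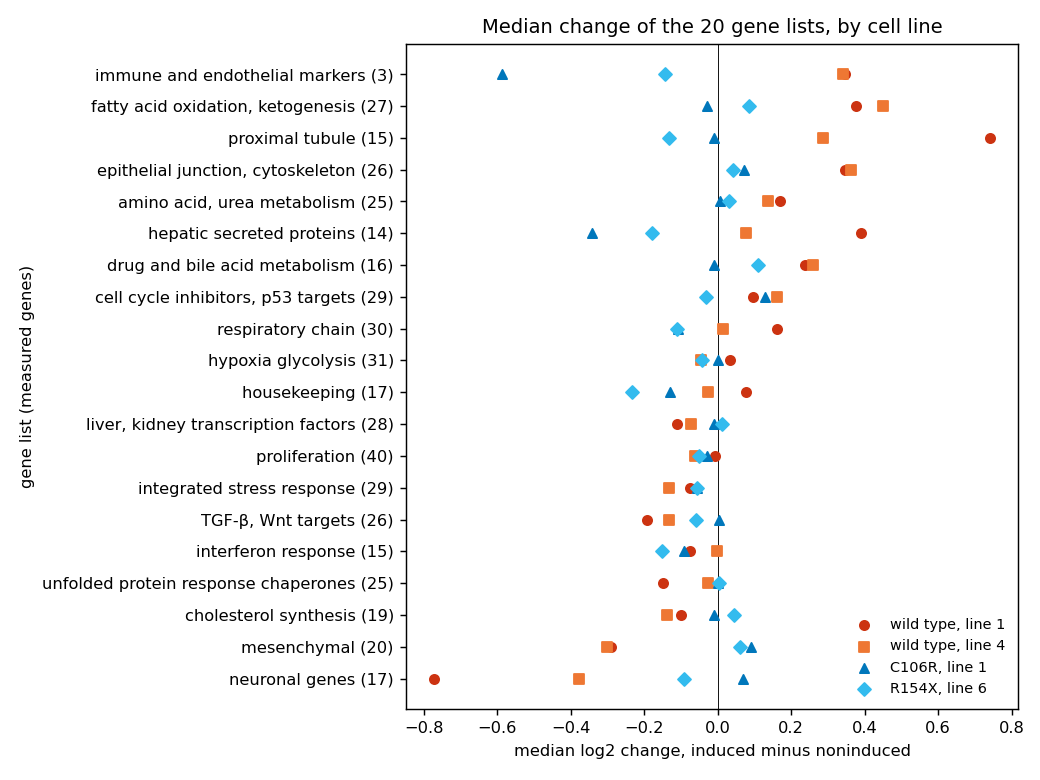
Median log2 change on induction (x axis) of the 20 gene lists (y axis, with the number of measured genes) in each of the 4 lines. The neuronal list has a wild-type median of -0.72 and the fatty acid oxidation list one of 0.43, against 0.01 and 0.03 in the mutant lines.

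Induction of the mutant C106R gave no called probe set, and 537 passed an unadjusted limma p under 0.05. Among named genes, the largest changes were of genes with a low signal on 1 of the 2 arrays. The SEs given for C106R and R154X come from the wild-type arrays, so they do not measure the spread of the mutant signals. WNT16, a secreted Wnt ligand, differed by 3.36 ± 0.56 (15.5 to 289), MICAL1 by 2.99 ± 0.51, IL18 by 2.78 ± 0.98, P2RY6 by 2.71 ± 1.41 and MROH8 by 2.68 ± 0.80. PRSS22 differed by -3.84 ± 0.62 (275 to 6.10), IHO1 by -3.35 ± 1.11, GLDN by -3.29 ± 0.56, ZNF626 by -3.12 ± 1.98 and KRT75 by -2.86 ± 1.09. All 10 had an adjusted p of 1.0.

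Induction of the mutant R154X gave 2 called probe sets, both of the beta-globin gene HBB, and 657 passed an unadjusted limma p under 0.05. HBB fell by 3.85 on the log2 scale (SE 0.25, adjusted p = 0.0182), from a signal of 2096 to 133. With 1 array on each side this has no replicate check, and 3 of the 4 HBB probe sets were at least 2-fold lower. Without the intensity trend 0 probe sets passed. ICA1-AS1 differed by 3.23 ± 0.61, TF by 2.96 ± 1.56, ARHGEF4 by 2.93 ± 0.92, SYT1 by 2.84 ± 1.05 and PFKFB4 by 2.81 ± 0.99. LOC105376166 differed by -3.17 ± 1.58, ADAMTS10 by -2.90 ± 0.60, LINC02504 by -2.88 ± 1.04 and C4orf17 by -2.85 ± 0.77. Apart from HBB, all 9 of these had an adjusted p of 1.0. With cell line as a block and 1 effect for both mutants, 1 probe set passed, which has no gene name here, and 2299 passed an unadjusted p under 0.05. The probe set that passed rose by 4.25 (block SE 0.19) in the mutants (adjusted p = 5.80e-06), by 4.74 with C106R and 3.76 with R154X, and by 4.17 and 4.25 in wild-type lines 1 and 4.

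The change on wild-type induction was then compared with the mean change of the mutants. Without the block limma called 0 probe sets for this difference, with 2065 at an unadjusted p under 0.05. With cell line as a block in the paired fit 1140 passed, 606 with the higher change in the wild type and 534 with the lower. All 35 probe sets called for wild-type induction were among them, as were 1022 of the 2574 called with the block. The genes with the smallest p-values were PPP1R1A at 3.22 ± 0.30 (adjusted p = 0.182, and 6.25e-04 with the block), MAN1A1, a Golgi mannosidase, at 1.66 ± 0.19, DDAH2 at 2.75 ± 0.34 and C1orf115 at 2.57 ± 0.33. The difference was -2.40 ± 0.31 for EBF2, -2.16 ± 0.28 for LGR5, -2.93 ± 0.49 for PELI3, -1.94 ± 0.35 for ARID3B and -1.64 ± 0.29 for SUSD5. These 9 genes passed with the block. For ARID3B the difference leaned on 1 mutant pair, with a change of 1.67 with R154X and 0.0075 with C106R. Its noninduced signal was 248 in the R154X line and 619 in the C106R line. Its wild-type change of -1.10 was not called (limma adjusted p = 0.181 without and 0.0607 with the block). HBB, at 2.58 ± 0.25, had an adjusted p of 0.182 without and 0.0766 with it. Wild-type and mutant arrays were hybridised in separate runs.

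The lines were also compared one by one, each against its own noninduced array, which uses no estimate of spread. At least 2-fold changes were seen for 2305 and 2629 probe sets in wild-type lines 1 and 4, for 1568 with C106R and for 1525 with R154X. These counts depend on the filter, and with it at the 75th percentile 15 changed with C106R and 36 with R154X. In both wild-type lines 659 changed at least 2-fold in the same direction, 396 up and 263 down, and 189 in opposite directions. In both mutant lines 216 changed in the same direction and 204 in opposite directions. The 4 pairs of a wild-type and a mutant line gave between 208 and 232 in the same direction and between 210 and 257 in opposite directions. Across probe sets, which are not independent replicates, Pearson's r between the changes was 0.318 for the wild-type pair (Spearman 0.318), 0.059 for the mutant pair (Spearman 0.125) and between -0.034 and -0.003 for the mixed pairs. With the stricter filter r was 0.690 for the wild-type and 0.289 for the mutant pair, and without a filter 0.119 and 0.024. In both wild-type lines 159 were at least 2-fold up and 29 down with the stricter filter, and 980 and 1028 without a filter. The balance of rises and falls thus depended on the filter.

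**Figure D3:**
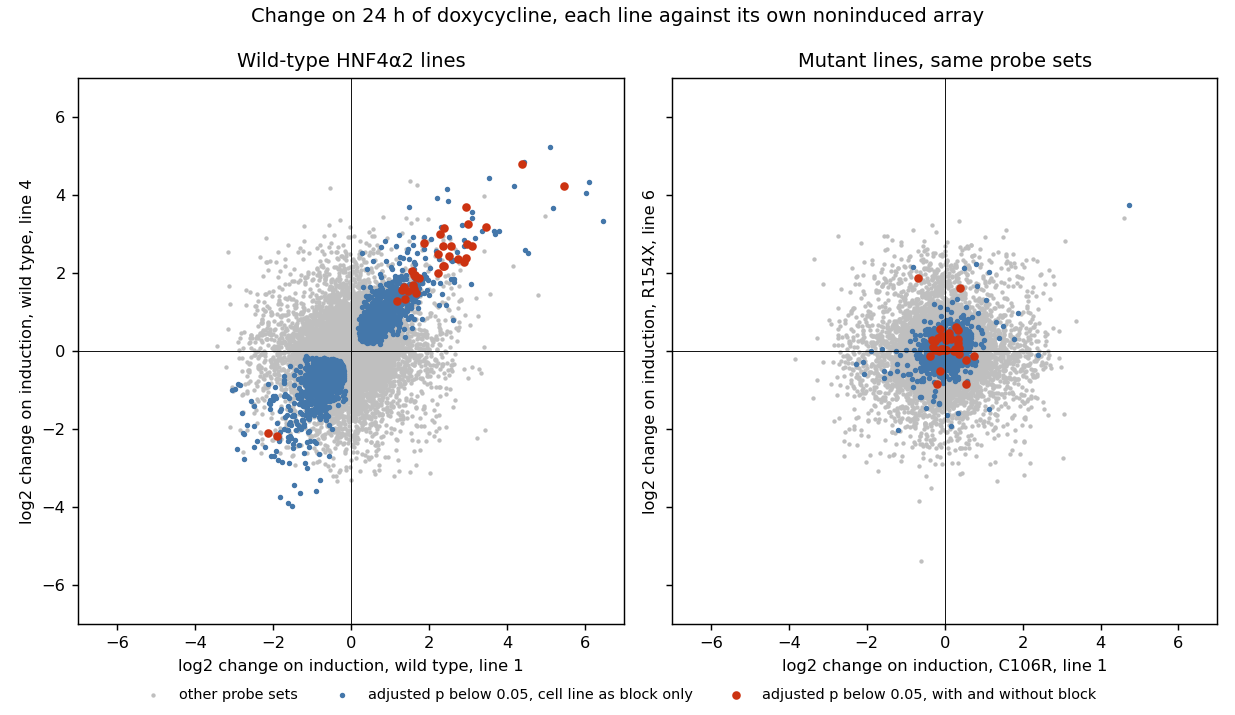
Log2 change on induction of 30511 probe sets in wild-type line 1 (x axis) against line 4 (y axis) on the left, and in the C106R line against the R154X line on the right. Each point is 1 probe set, coloured by the wild-type call, and the 35 called without the block lie along the diagonal on the left and mostly near 0 on the right.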

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

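The tests of the doxycycline effect, of other pairs of lines, of called genes without another probe set, of the readout of the mutant run and of the other globin genes, and the bound of 50% for single probe sets, were chosen after the results were seen, and the remaining tests before. Wild-type and mutant lines differed in their change on induction at 1140 probe sets with cell line as a block, and at 0 without it. The block treats the 2 mutants as replicates, and run and construct cannot be told apart in this difference. Among named genes the difference in log2 change, wild type minus mutants, was 4.26 for CIDEB, 3.22 for PPP1R1A, 3.01 for AQP11, 2.75 for DDAH2, 2.57 for C1orf115, 2.55 for SLCO4C1, 2.32 for PRPH and for TRIM10, 2.24 for RBKS and 2.18 for ERBB3. It was 1.996 for GRTP1, 1.92 for TMT1B, 1.79 for GCHFR, 1.66 for MAN1A1, 1.65 for COBL and 1.62 for ABCB1. It was -2.93 for PELI3, -2.40 for EBF2, -2.16 for LGR5, -1.94 for ARID3B and -1.64 for SUSD5. That of ARID3B leaned on a rise of 1.67 with R154X, and its wild-type change of -1.10 was not called in either fit.

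Gene lists also differed between wild-type and mutant lines with camera's preset correlation. The adjusted p of the difference was 3.16e-06 for fatty acid oxidation, 0.00141 for the epithelial list, 0.00222 for amino acid metabolism, 0.00388 for proximal tubule and 0.00507 for neuronal genes. It was 2.80e-05 for the respiratory chain and 0.00249 for housekeeping genes. The medians of these last lists were 0.073 and -0.0048 in the wild-type lines and, lower, -0.112 and -0.134 in the mutant lines. With an estimated correlation none of these 7 passed (adjusted p = 0.402 for the first 5, 0.505 for the respiratory chain and 0.499 for housekeeping).

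Probe sets called in the wild-type lines stayed near their noninduced level in the mutant lines. A response to doxycycline itself would appear in the mutants too, and the median share of the wild-type change seen there was 0.0211, with quartiles of -0.029 and 0.094, which argues against it. A weaker readout in the mutant hybridisation run might compress the signals of these probe sets there. The slope of their log2 signal over the noninduced wild-type mean was at least 1.04 on each mutant array (lowest 95% bound 0.96). This argues against a compression of levels between probe sets. Slopes of levels do not measure changes on induction, so an effect of the run on the changes stays open. The 1 probe set called in the mutants changed by 4.74 and 3.76 there, against 4.17 and 4.25 in the wild-type lines. It was picked by its change in the mutants, so it shows only that a change of this size could be read in that run. Single probe sets with faulty signals would leave other probe sets of the called genes as likely to move against the call as with it. Of 26 such probe sets, 84.6% moved in the called direction in both lines (exact 95% interval 65.1% to 95.6%), and of the brightest in each of 17 genes 16 did, which argues against it for these genes, although the interval reaches below the bound of 75% written beforehand. It stays open for the 9 called genes with no other probe set past the filter. Among the 3 ways to pair the 4 lines, 1 gave as many as 1140 calls and the highest of the others gave 0, and 3 pairings are too few for a share under 0.05. A difference between the proteins is a hypothesis that may account for the pattern, but other differences that follow the runs were not tested, and whether the mutants were expressed was not checked.

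Beta-globin signal on the R154X induced array was far below that of the other 7 arrays. A loss of signal over the whole array is argued against by 4075 probe sets of similar level, whose median change was 0.016. A defect in 1 probe set is argued against by the other globin genes, since 7 of their 8 probe sets were lowest on this array, where chance gives 1. Those 7 each carry several gene symbols and most share the same genes, so they are not independent. The remaining probe set, of HBD, was not lowest here, at 59.7 against 50.8 on the C106R induced array. An earlier form of this test asked for all 4 HBB probe sets to fall, and 3 did. Red blood cell RNA in the other arrays stays open: 8 of 15 erythroid markers were measured and their median change was 0.117, but 5 had mean signals of 114 to 193, near the array medians, and 3 of 1884 to 4320, above that of HBB, so neither kind could show a small loss. The bound written beforehand was met but was wrong for that reason, and no biological explanation was tested.

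Respiratory chain genes were slightly lower after induction in both mutant lines, with a median of -0.112 over 30 genes and an adjusted p of 9.72e-07 with the preset correlation (adjusted p = 0.690 with an estimated one). Random lists of 30 genes matched on signal had a median of -0.078, with 95% of them between -0.117 and -0.033. The observed median lay at percentile 5.02 of them, so a shift of abundant transcripts that depends on intensity may account for it, although this lies close to the bound of 5 that had been set. The housekeeping median of -0.134 lay at percentile 24.3 of its own matched lists.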

How the results depend on the processing

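All alternatives here were chosen before the data were examined, apart from the blocked fits without a mutant line. The count of 35 for wild-type induction was 58 with the offset at the 25th percentile, 0 without the filter on dim probe sets, 0 without the intensity trend, and between 0 and 71 when 1 wild-type array was left out (0 without either induced array, 71 without noninduced line 1). In paired fits, with cell line as a block, it was 2574 over all 4 lines and 3044 over the 4 wild-type arrays alone, and, chosen after seeing the data, 3140 without the R154X line and 3126 without the C106R line. The block gave 1 call for C106R and R154X, which share 1 effect there, and R154X had 0 calls without the trend and 1 with 1 probe set per gene. The difference between wild type and mutants had 1140 calls with the block, 999 without the R154X line and 936 without the C106R line, while without the block it had 0 calls, and between 0 and 2 when 1 wild-type array was left out. The median residual SD was lower with the block, where it also drew on the mutant lines, and the cause of the other moves was not tested. With the 25th percentile offset, 114 probe sets changed 2-fold in both mutant lines and 1029 in C106R. Without the filter 2008 changed 2-fold in both wild-type lines, 1438 in both mutant lines, 8708 in C106R and 8486 in R154X, and with the filter at the 75th percentile these counts were 188, 2, 15 and 36. The correlation of the wild-type lines was 0.291 with no offset, 0.357 with the 25th percentile, 0.119 without the filter and 0.690 with the stricter one, and that of the mutant lines 0.024 and 0.289 for these filters. The camera test passed 9 lists, 8 without the filter, where proximal tubule had an adjusted p of 0.0648, and 7 with any 1 array left out. Its direction turned for the interferon list without the filter (median 0.107) and with quantile normalization (-0.136). With 1 array left out, medians ran from -0.202 to 0.061 for the interferon list, -0.060 to 0.010 for housekeeping, -0.144 to -0.022 for cholesterol and -0.058 to 0.054 for hypoxia, and the test's direction turned in each. Genes that turned sign then, none of them called, were TTR (-2.12 to 0.80), SLC5A2 (-0.14 to 2.56), CENPF (-1.02 to 0.28) and TAGLN (-7.5e-05 to 2.21). Among the called genes, AQP11 had an adjusted p of 0.0512 without the offset and COBL one of 0.0516 with quantile normalization. Without the induced array of line 1 or of line 4, 18 named genes each time lost their call, and 4 did without noninduced line 4. The block changed no call of a list's test and added calls of 40 named genes for wild-type induction. Signals near the array medians limit what can be said of genes with a low baseline.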

Other observations

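The restriction of solute carriers to 1 symbol form was chosen after the first result was seen, and the tests of leak and of solute carriers were written before. With cell line as a block, the smallest p-value of a named gene was that of SELENOP, a plasma selenium carrier, which rose by 2.30 ± 0.10 (block SE, as for the next genes) in the wild-type lines and changed by 0.23 in the mutants. ACOT13, an acyl-CoA thioesterase, rose by 1.497 ± 0.084, SELENBP1 by 2.14 ± 0.14 and the microsomal transferase MGST2 by 1.43 ± 0.10. Among the genes that fell, the log2 change was -1.63 ± 0.13 for the scavenger receptor COLEC12, -1.64 ± 0.14 for the MAP kinase phosphatase DUSP6, -1.50 ± 0.15 for the neuroendocrine factor INSM1, -1.16 ± 0.11 for the kinesin gene KIF5C and -0.79 ± 0.08 for the tubulin gene TUBB2B. These genes were named after their values were seen, from the smallest p-values of the blocked fit.

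Over all 12 globin probe sets, the 4 of HBB included, the median change was -1.49 with R154X and -0.66 with C106R, where all 12 were lower. It was 0.19 and 0.32 in wild-type lines 1 and 4, where 10 and 9 of the 12 were higher. These values come from 1 pair of arrays each.

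A leak of the wild-type transgene without doxycycline was tested as a hypothesis. Genes raised at least 2-fold in line 1 would then lie higher in noninduced line 4 than in the noninduced mutant lines. The median difference over 432 genes was 0.055, inside the range of -0.0067 to 0.099 of 95% of 10000 lists matched on signal. Of these genes, 75% rose in line 4 on induction, by a median of 0.83 over all 432. The 62 of them above the median signal all rose in line 4, and their median difference was -0.0055, inside the range of -0.059 to 0.073 of their own matched lists. It may still be that a leak smaller than this range was present. The wild-type side was 1 array, hybridised in another run than the mutant arrays. Run, cell line and construct cannot be told apart in this baseline difference.

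Solute carrier genes were tested for a higher share of rises with the block. Of 251 measured, 16 rose (6.37%), against 766 of 13190 other genes (5.81%), an odds ratio of 1.10 (95% interval 0.62 to 1.84; two-sided Fisher's exact p = 0.682). The interval leaves room for a modest excess or deficit. Falls were seen for 21 (8.37%) against 718 (5.44%), with a Fisher's exact p of 0.0499, or 0.150 adjusted over the 3 tests run. The third test, of rises among genes above the median signal, gave an odds ratio of 1.22 (Fisher's exact p = 0.487, or 0.682 adjusted). One symbol of an overlapping transcript had been counted at first and was then left out.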
